A study of Bacteroides thetaiotaomicron with 6 samples.

How the data were processed

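RNA came from 6 cultures of wild-type Bacteroides thetaiotaomicron VPI-5482, 3 on glucose and 3 on ribose. Per the labels, cells grown overnight in rich medium were moved to minimal medium with 1 of the sugars, RNA was preserved at harvest, treated with DNase and depleted of ribosomal RNA, and the libraries were sequenced on an Illumina HiSeq instrument. The series text describes the samples as biological triplicates. The aligner, the counting program, the genome build and the annotation are not given in the sources used here.

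The authors deposited 2 tables. The short table holds 81 genes past cutoffs of the authors, with an RPKM value (reads scaled by gene length and library size) for each library, per the file headers. Which reads make up the library size is not given in the sources used here. Both tables hold the authors' fold change of ribose over glucose, a p-value and a score named a T value, per the file headers. The deposited fold was recomputed for the 81 genes and equalled the ratio of geometric means of the RPKM values to within 0.0699%. The deposited score is negative where ribose is higher. The deposited p-values matched, to within 1% in 100% of the rows, a Benjamini-Hochberg adjustment over all 4942 rows of a two-sided p with 5.32 degrees of freedom computed from the score. They are therefore treated as adjusted p-values, although no header says so.

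The full table has 4942 rows. Of these 71 (1.44%) have a blank name, and 93 rows (1.88%) are RNA features, 15 ribosomal RNA, 63 transfer RNA and 15 other RNAs. They were left out of the gene counts, which leaves 4778 gene rows, 4253 of them named by locus tag and 525 by symbol alone. A fold of 1 with a score of 0 was listed for 72 gene rows. The full table also has 6 columns of per-library values whose names match no sample's labels. They were not used here, so tests that need values per library cover the 81 genes only. A fold and p for other genes are the authors' own.

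The test for the 81 genes was limma 3.58.1 in R 4.3.3, with an empirical Bayes trend, on log2(RPKM + 1), for genes with a mean RPKM of at least 1, and Benjamini-Hochberg adjustment over the 81 genes at a threshold of 0.05. Fold changes on this scale understate the change of low genes. The design written before the data were examined allowed for counts or for RPKM values of all genes; the unit found was RPKM for the chosen genes and authors' comparisons for the rest, so genome-wide counts describe the authors' p-values. With 3 libraries against 3, an exact two-sided permutation test of 1 gene cannot go below p = 0.1.

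Of 41 gene lists fixed before the data were examined, 21 were ranges of locus tags and the rest were rules on product names. The files hold no product names, so pathway lists were matched by gene symbol, with symbols chosen after the names in the files had been seen and before their fold changes had been looked at. The chosen symbols gave no members for 5 lists (SusC-like and SusD-like proteins, glycoside hydrolases, sigma and anti-sigma factors, hybrid two-component systems and mobile elements), which were not analysed here. Genes named by a Sus symbol in the files, SusC and SusD among them, were counted in the starch (sus) locus list. Lists of genes with at least 3 members, 33 in all, were tested with limma's cameraPR on the ranks of the authors' scores over 4778 genes, with a preset correlation of 0.01 in place of the planned camera test on values per library. Adjustment was over the 33 lists. The ribosomal RNA and transfer RNA lists were not tested, since RNA rows were left out of the ranked genes, and are given as values. A correlation could be estimated for 3 lists, from members with values per library.

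Genes were named by a rule fixed before the data were examined: the 10 largest rises and the 10 largest falls among genes past the threshold with no overlap between the sugars, each gene of the ribose locus, and the 2 members of each list with the smallest p. The first part could use the 81 genes only. BT1764, fbaB, fba, udk, atpA, the clpB gene with the smaller rise, sodB, BT3167, BT3024 to BT3027, BT2810 to BT2813, the runs of neighbouring genes and the symbol families lie outside the rule and were chosen after their values were seen.

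Relative depth was read from 8 low genes, whose RPKM values in a library are whole multiples of the worth of 1 read. The relative depths made 8 and 8 of the 8 genes whole in glucose replicates 2 and 3, within a tolerance for rounding that grows with the count. They made 7, 8 and 6 of the 8 genes whole to within 0.05 reads in ribose replicates 1, 2 and 3. With the smallest whole numbers that fit, these genes would have from 1 to 15 reads in the glucose libraries. The true counts may be common multiples of these, and absolute depth stays unknown.

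The replicate numbers of the labels were checked for pairing. Deviations from the group means over the 81 genes correlated at 0.246, 0.243 and 0.166 between libraries with the same number, each above the limit of 0.1 set for pairing. Of the pairs with different numbers, glucose replicate 3 and ribose replicate 2 also correlated above that limit, at 0.204. That is more than the 0.166 of the replicates numbered 3, so the check does not establish a pairing. The labels state none. The main fit was therefore unpaired, and a fit with the replicate number as a block was run as an alternative.

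On simulated data for the 81 genes, limma recovered 30% of 1.5-fold, 74% of 2-fold and 98.7% of 5-fold changes, and 3.42% of calls were false, over 100 simulations. On simulated data for 4778 genes, cameraPR called the shifted list in 94% of 100 simulations and 0.125% of the unshifted lists. Only part of the 81 genes was given a change, always a rise, and no list but the shifted one was changed. The real data hold many changes in both directions, so these rates are not the sensitivity for them. All genes were simulated as independent of each other. The list rates therefore say nothing about false calls among correlated genes, such as those of the ribose locus. Alternatives covered the replicate block, each library left out, the filter, the pseudocount, the trend, thresholds, fold limits, centring and the settings of the list test. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.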

Results

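Transcripts of Bacteroides thetaiotaomicron VPI-5482, an anaerobic gut bacterium that uses many dietary and host glycans, were measured by RNA sequencing after growth on 1 of 2 sugars. The libraries came from 3 cultures on glucose, the reference sugar, and from 3 cultures on ribose, a pentose. Each sugar was supplied at 5 mg/ml in minimal medium and cells were collected in mid-log phase, at an absorbance of 0.6 to 0.8. The comparison asks which genes change in expression when ribose replaces glucose. Per-library RPKM values were used for 81 genes that the authors had placed on a short list of large changes, and fold changes for 4778 genes came from the authors' deposited table. Absolute depth is unknown, but the low RPKM values gave depths relative to glucose replicate 1 of 1.04 and 1.17 for glucose replicates 2 and 3, and of 0.740, 1.39 and 1.15 for ribose replicates 1, 2 and 3. No coordinates are given because the genome build of the files was not stated, so genes are named by locus tag or symbol as in the files, except that the rus names of the ribose locus come from published work on this strain.

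The ribose utilisation locus showed the largest rises on ribose among the 81 genes with per-library values. BT2803 (rusK1), a ribokinase gene, rose from 24.5 ± 9.63 to 4517 ± 659 RPKM (SD, n = 3 per sugar), and the adjoining ribokinase gene BT2804 (rusK2) rose from 28.6 ± 14.6 to 4534 ± 408 RPKM. The permease gene BT2809 (rusT) rose from 33.2 ± 14.0 to 4520 ± 334 RPKM. BT2805 (rusC) and BT2806 (rusD), which encode a SusC-like outer membrane transporter and its SusD-like surface lipoprotein, rose from 35.5 ± 18.1 to 3495 ± 453 RPKM and from 34.8 ± 17.0 to 3479 ± 625 RPKM. BT2807 rose from 43.4 ± 20.1 to 4784 ± 983 RPKM and BT2808 from 42.5 ± 18.8 to 5114 ± 815 RPKM.

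On the log2(RPKM + 1) scale the rise was 7.54 ± 0.32 (SE) for BT2803, 7.42 ± 0.42 for BT2804 and 7.15 ± 0.34 for BT2809. It was 6.98 ± 0.37 for BT2808, 6.86 ± 0.40 for BT2807, 6.74 ± 0.43 for BT2805 and 6.73 ± 0.42 for BT2806. All 7 genes passed limma with Benjamini-Hochberg adjustment over the 81 genes, with adjusted p-values from 2.88e-06 for BT2803 to 5.85e-06 for BT2805, and each was higher in 3 of 3 ribose libraries than in any glucose library. BT2802 (rusR), the regulator gene at the edge of the locus, had a fold change of 0.738 and a p of 0.19 in the authors' deposited table and did not pass. Of the 8 genes of the locus, 7 rose in the authors' deposited table, and 7 also when adjusted over the list alone. The locus as a list had a median log2 fold of 6.96 in the authors' deposited table, and limma's cameraPR gave an adjusted p of 0.000598 with its preset correlation of 0.01. With an estimated correlation of 0.954 the cameraPR adjusted p was 0.201. At that correlation the rank test could not pass even if all 8 genes held the highest ranks, so it decides nothing. Those 7 genes were on the short list, which was chosen on these samples, so they are not independent evidence of the direction. In glucose replicate 1 BT2804 stood at 12.2 RPKM, against 40.1 and 33.4 RPKM in the other glucose libraries, and BT2805 at 14.7 RPKM against 43.9 and 47.8 RPKM.

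**Figure D1:**
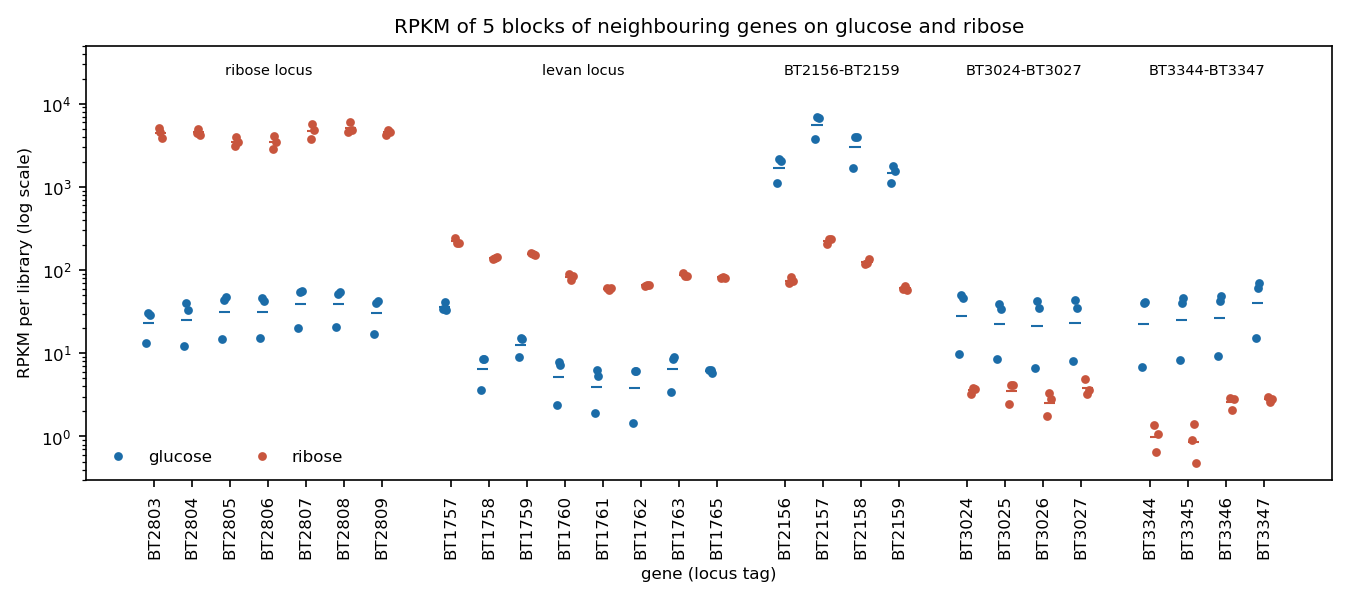
RPKM per library (log axis) for genes of 5 blocks of neighbouring locus tags, with 3 glucose libraries in blue, 3 ribose libraries in red and a bar at each group's geometric mean. The 7 ribose locus genes sit between 12.2 and 55.3 RPKM on glucose and between 2842 and 6045 RPKM on ribose, while BT2157 falls from as much as 6861 to as little as 203 RPKM.

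Genes of the levan locus, which serves the use of fructose polymers, also rose on ribose. BT1758, a fructose transporter gene, rose from 6.94 ± 2.90 to 139 ± 4.74 RPKM (SD, n = 3 per sugar). BT1760, a glycoside hydrolase gene, rose from 5.81 ± 2.98 to 83.3 ± 6.65 RPKM, and the SusD-like gene BT1762 from 4.53 ± 2.66 to 65.6 ± 1.16 RPKM. Their log2 changes were 4.21 ± 0.33 (SE), 3.75 ± 0.39 and 3.74 ± 0.44, with limma adjusted p-values of 1.24e-05, 6.46e-05 and 0.000118. With a pseudocount of 5 in place of 1 these log2 changes became 3.62, 3.07 and 2.93. Of the 12 locus genes 8 rose and 1 fell in the authors' deposited table, and the same numbers passed when adjusted over the list alone. The smallest p-values there belonged to BT1765, with a fold of 13.2, and to the fructokinase gene BT1757, with a fold of 6.24 in the authors' deposited table. BT1764 fell, with a fold of 0.648 (p = 0.00709 in the authors' deposited table). The median log2 fold of the locus in the authors' deposited table was 3.67, with a cameraPR adjusted p of 0.00178, and the call was lost at adjusted p = 0.206 with an estimated correlation. The 8 risen genes were on the short list chosen on these samples and are not independent evidence. BT1762 stood at 1.46 RPKM in glucose replicate 1 and at 6.06 and 6.08 RPKM in the other glucose libraries.

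The 10 largest falls on the log2(RPKM + 1) scale were those of BT2156 to BT2159, then BT2178, BT3344, BT3345 and BT3347, BT0970 and BT3346. BT2157 fell from 5789 ± 1776 to 226 ± 19.6 RPKM, BT2158 from 3221 ± 1318 to 125 ± 10.9 RPKM, BT2159 from 1477 ± 328 to 60.2 ± 3.58 RPKM and BT2156 from 1785 ± 592 to 75.1 ± 7.22 RPKM (SD, n = 3 per sugar). Their log2 changes were -4.63 ± 0.26, -4.58 ± 0.34, -4.57 ± 0.19 and -4.49 ± 0.27 (SE), with limma adjusted p-values between 2.88e-06 for BT2159 and 1.10e-05 for BT2158. BT2178 fell from 2261 ± 274 to 127 ± 22.5 RPKM and BT0970 from 780 ± 10.7 to 94.6 ± 4.20 RPKM, with log2 changes of -4.15 ± 0.18 and -3.03 ± 0.11 and a limma adjusted p of 2.88e-06 for each. The chondroitin sulfate locus genes BT3345, BT3344, BT3347 and BT3346 had log2 changes of -3.80 ± 0.64, -3.57 ± 0.66, -3.45 ± 0.57 and -2.97 ± 0.60, with limma adjusted p-values of 0.000872, 0.00139, 0.000759 and 0.00219. In ribose these 4 genes lay between 0.485 and 2.94 RPKM, where the pseudocount sets much of the size. With pseudocounts of 0.1 and 5 the log2 changes were -4.71 and -2.41 for BT3345, -4.38 and -2.27 for BT3344, -3.80 and -2.57 for BT3347 and -3.33 and -2.13 for BT3346. Glucose replicate 1 held them at 6.87 to 15.1 RPKM and the other glucose libraries at 39.6 to 69.4 RPKM. Without glucose replicate 1 their log2 changes became -4.56 for BT3345, -4.37 for BT3344, -4.13 for BT3347 and -3.70 for BT3346.

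All 81 genes of the short list passed limma, 64 higher and 17 lower in ribose, with adjusted p-values from 2.88e-06 to 0.00678. The ribose and glucose values of all 81 did not overlap, an outcome that chance gives 10% of genes. The list was chosen by the authors on these same samples, so the count is not independent evidence, and p-values adjusted over chosen genes do not stand for a genome-wide test. Its smallest rise was 5.01-fold, its weakest fall had a fold of 0.190 and its highest p was 0.032, all in the authors' deposited table.

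Across the genome, 1986 of 4778 genes (41.6%) had a p under 0.05 in the authors' deposited table, 786 higher and 1200 lower in ribose. Changes of at least 5-fold were carried by 92 genes in the authors' deposited table, 75 higher and 17 lower. The median log2 fold of all 4778 genes was -0.073 in the authors' deposited table. Of 33 gene lists tested with limma's cameraPR on the ranks of the authors' scores, 10 stood higher and 12 lower than other genes. Calls at the preset correlation of 0.01 were fewer at higher values: 14 lists at 0.05 and 0 at 0.2. None of the 3 lists with an estimated correlation held. For the ribose and chondroitin lists, at 0.954 and 0.964, the rank test could not have passed even with all members at the extreme ranks.

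Genes of translation fell together. Ribosomal protein genes fell in 46 of 53 cases in the authors' deposited table and rose in 0, or fell in 49 when adjusted over the list alone. Their median log2 fold in the authors' deposited table was -0.76, with a cameraPR adjusted p of 1.85e-12. Examples from the authors' deposited table were rpsA, with a fold of 0.569, and rpsL, with 0.602. Aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids, fell in 19 of 20 cases in the authors' deposited table, and in 19 when adjusted over the list alone. Their median log2 fold was -0.70 in the authors' deposited table (cameraPR adjusted p = 3.03e-07), with folds of 0.560 for ileS and 0.596 for argS. Of the 63 tRNA genes in the authors' deposited table, 24 were listed at a fold of 1 with a score of 0, and 0 had a p under 0.05. The median log2 fold was 0.37 over all 63 and 1.17 over the other 39 in the authors' deposited table. The smallest p-values there belonged to tRNA-Thr-CGT, with a fold of 3.58 (p = 0.124), and tRNA-Ser-GGA, with a fold of 4.44 (p = 0.157 in the authors' deposited table). None of the 15 ribosomal RNA rows of the authors' deposited table had a p under 0.05, and 11 of them were listed at a fold of 1 with a score of 0. The other 4 had folds from 1.82 to 3.06 in the authors' deposited table, among them a 23S row at 2.32 (p = 0.115) and a 16S row at 3.06 (p = 0.197).

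The lists for purine, pyrimidine, histidine and branched-chain amino acid synthesis also stood lower. Of 11 purine synthesis genes 9 fell in the authors' deposited table, and 9 when adjusted over the list alone, with a median log2 fold of -0.68 (cameraPR adjusted p = 0.000946). The GMP synthase genes guaA and guaA2 had folds of 0.534 and 0.551 in the authors' deposited table. Pyrimidine synthesis genes fell in 9 of 11 cases in the authors' deposited table, or in 10 when adjusted over the list alone, with a median log2 fold of -0.81 (cameraPR adjusted p = 0.000267) and folds of 0.551 for pyrD and 0.570 for pyrK. Histidine synthesis starts from a ribose phosphate compound, and 7 of its 8 genes fell in the authors' deposited table, or 8 when adjusted over the list alone. The median log2 fold of the histidine genes was -0.52 in the authors' deposited table (cameraPR adjusted p = 0.00125), with folds of 0.525 for hisA and 0.576 for hisF. All 4 branched-chain amino acid synthesis genes fell in the authors' deposited table, also when adjusted over the list alone, with a median log2 fold of -1.30 (cameraPR adjusted p = 0.00349). Among them ilvD had a fold of 0.370 and leuA of 0.382 in the authors' deposited table.

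Genes of sugar breakdown moved in both directions. Both pentose phosphate pathway genes found by symbol rose in the authors' deposited table, also when adjusted over the list alone: the transaldolase gene tal 2.70-fold (p = 0.00345) and the glucose 6-phosphate dehydrogenase gene zwf 1.66-fold (p = 0.00968). A list of 2 genes was too short to test. Of 17 glycolysis and gluconeogenesis genes 4 rose and 9 fell in the authors' deposited table, or 4 and 10 when adjusted over the list alone, and the list did not pass (cameraPR adjusted p = 0.206, median log2 fold -0.32). The phosphoglycerate mutase gene gpmA2 had a fold of 3.27, while pfp, a phosphofructokinase gene, had a fold of 0.483 in the authors' deposited table. The fructose bisphosphate aldolase genes parted, with a fold of 3.17 for fbaB and 0.730 for fba in the authors' deposited table. Of 3 nucleoside salvage genes punA rose, with a fold of 1.43, and apt and udk fell, with folds of 0.607 and 0.803 in the authors' deposited table. The same numbers passed when adjusted over the list alone, and the salvage list did not pass (cameraPR adjusted p = 0.630, median log2 fold -0.32 in the authors' deposited table).

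ATP synthase genes rose in 4 of 8 cases and fell in 1 in the authors' deposited table, or 6 and 1 when adjusted over the list alone, with a median log2 fold of 0.61 (cameraPR adjusted p = 0.0205). The members atpD and atpE had folds of 1.96 and 1.69, while the 2 genes named atpA parted in the authors' deposited table, with folds of 0.704 (p = 0.00877) and 1.42 (p = 0.0893). The list call was lost at a preset correlation of 0.05 (cameraPR adjusted p = 0.0513) and with scores in place of ranks (0.192). In the list for fumarate, succinate and propionate formation 2 genes rose and 3 of 7 fell in the authors' deposited table, or 2 and 5 when adjusted over the list alone. It did not pass (cameraPR adjusted p = 0.444), and its median log2 fold of -0.44 and mean of 0.15 in the authors' deposited table differed in sign. Its member sucC, a succinyl-CoA synthetase gene, had a fold of 8.09 and the mutase gene mutB one of 0.713 in the authors' deposited table.

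Chaperone genes rose in 5 of 8 cases in the authors' deposited table, and in 5 when adjusted over the list alone, with a median log2 fold of 0.48 (cameraPR adjusted p = 0.00346). The 2 clpB genes rose 3.24-fold and 1.53-fold and grpE 1.70-fold in the authors' deposited table. Of 6 oxidative stress genes 5 rose in the authors' deposited table, also when adjusted over the list alone, with a median log2 fold of 1.11 (cameraPR adjusted p = 0.00688). The catalase gene katA rose 2.50-fold, the rubrerythrin gene rbr 2.14-fold and the superoxide dismutase gene sodB 2.39-fold in the authors' deposited table.

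The lists for yeast mannan, homogalacturonan, arabinogalactan, mucin glycans and xylose stood higher on ribose. Yeast mannan genes rose in 10 of 34 cases and fell in 1 in the authors' deposited table, or 9 and 1 when adjusted over the list alone, with a median log2 fold of 0.86 (cameraPR adjusted p = 0.000267). BT3778 had a fold of 4.70 and BT3785 of 60.6 in the authors' deposited table, although BT3785 is not on the short list and its level was not analysed here. In the homogalacturonan locus, for a pectin backbone, 5 of 17 genes rose and 1 fell in the authors' deposited table, or 5 and 0 when adjusted over the list alone. Its median log2 fold was 0.53 (cameraPR adjusted p = 0.0118), with folds of 2.43 for BT4109 and 1.46 for BT4116 in the authors' deposited table. Arabinogalactan genes rose in 4 of 29 cases in the authors' deposited table, or in 1 when adjusted over the list alone, with a median log2 fold of 0.33 (cameraPR adjusted p = 0.0158) and folds of 2.98 for BT0266 and 1.87 for BT0263. Of 40 genes of mucin glycan loci 2 rose and 1 fell in the authors' deposited table, or 1 and 1 when adjusted over the list alone, with a median log2 fold of 0.22 (cameraPR adjusted p = 0.0406). BT1035 had a fold of 1.95 and BT2826 one of 0.737 in the authors' deposited table. Over all 4778 genes 786 rose there. In the mucin and arabinogalactan lists the share of risen genes was smaller than over all genes. In the yeast mannan, homogalacturonan and xylose lists it was larger. Xylose utilisation genes rose in 2 of 4 cases in the authors' deposited table, and in 2 when adjusted over the list alone, with a median log2 fold of 0.65 (cameraPR adjusted p = 0.0465) and folds of 2.35 for BT0794 and 1.40 for BT0792. At a preset correlation of 0.05 the calls of the homogalacturonan, arabinogalactan, mucin and xylose lists were lost (cameraPR adjusted p = 0.0524, 0.0886, 0.174 and 0.0748), and all 4 were lost with scores in place of ranks (0.215, 0.273, 0.427 and 0.344).

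Loci for host glycosaminoglycans, the sulfated sugar chains of animal tissue, stood lower. Heparin locus genes fell in 6 of 12 cases in the authors' deposited table, or in 10 when adjusted over the list alone, with a median log2 fold of -0.67 (cameraPR adjusted p = 0.00688) and folds of 0.462 for BT4657 and 0.636 for BT4663. Chondroitin sulfate locus genes fell in 10 of 27 cases and rose in 1 in the authors' deposited table, also when adjusted over the list alone, with a median log2 fold of -0.35 (cameraPR adjusted p = 0.0465). That call was lost at adjusted p = 0.696 with an estimated correlation of 0.964, taken from the 4 members with per-library values. At that correlation the rank test could not pass even if all 27 genes held the lowest ranks, so it decides nothing. With scores in place of ranks the heparin and chondroitin calls were lost (cameraPR adjusted p = 0.0943 and 0.182), and at a preset correlation of 0.05 the chondroitin call was lost (0.164). BT3325 had a fold of 0.491 and BT3347 one of 0.0694 in the authors' deposited table.

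Several carbohydrate lists did not pass. Of 21 arabinose and arabinan genes 2 rose in the authors' deposited table, or 0 when adjusted over the list alone (cameraPR adjusted p = 0.0869, median log2 fold 0.061), namely BT0356 with a fold of 1.46 and BT0354 with 1.27. Of 8 starch (sus) locus genes 1 fell in the authors' deposited table, SusA with a fold of 0.286, or 0 when adjusted over the list alone (cameraPR adjusted p = 0.237, median log2 fold -0.89). SusB had a fold of 0.457 and a p of 0.111 in the authors' deposited table. In the pectic galactan locus 1 of 7 genes rose and 1 fell in the authors' deposited table, or 0 and 0 when adjusted over the list alone (cameraPR adjusted p = 0.336, median log2 fold 0.44). They were BT4670, with a fold of 3.28, and BT4673, with a fold of 0.718 in the authors' deposited table. Of 38 rhamnogalacturonan I genes 1 rose and 2 fell in the authors' deposited table, or 0 and 0 when adjusted over the list alone, including BT4156 with a fold of 0.640 and BT4145 with 0.732. The test of that list pointed up (cameraPR adjusted p = 0.710) while its median log2 fold was -0.029 in the authors' deposited table, a sign that flips when folds are centred on the median of all genes.

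Capsule loci make the surface polysaccharides of this bacterium, and 4 of 8 lists stood lower, 2 of them only at the preset correlation of 0.01 on ranks. In capsule 1, 20 of 28 genes fell and 1 rose in the authors' deposited table, or 22 and 1 when adjusted over the list alone, with a median log2 fold of -0.99 (cameraPR adjusted p = 5.60e-07) and folds of 0.413 for BT0398 and 0.410 for BT0382. In capsule 3, 15 of 20 genes fell in the authors' deposited table, also when adjusted over the list alone, with a median log2 fold of -1.10 (cameraPR adjusted p = 0.000462) and folds of 0.338 for BT0602 and 0.393 for BT0601. In capsule 8, 12 of 32 genes fell in the authors' deposited table, or 10 when adjusted over the list alone, with a median log2 fold of -0.54 (cameraPR adjusted p = 0.00997) and folds of 0.547 for BT0064 and 0.336 for BT0063. In capsule 4, 3 of 21 genes fell in the authors' deposited table, or 0 when adjusted over the list alone, with a median log2 fold of -0.64 (cameraPR adjusted p = 0.0427) and folds of 0.674 for BT1356 and 0.677 for BT1341. The share of genes that fell in capsule 4 was below that over all 4778 genes, of which 1200 fell in the authors' deposited table. The calls of capsules 8 and 4 were lost at a preset correlation of 0.05 (cameraPR adjusted p = 0.0748 and 0.135) and with scores in place of ranks (0.0740 and 0.269).

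The other 4 capsule lists did not pass. Capsule 5 had 3 genes that rose and 8 of 22 that fell in the authors' deposited table, or 3 and 9 when adjusted over the list alone (cameraPR adjusted p = 0.0705, median log2 fold -0.50), with folds of 4.82 for BT1667 and 0.486 for BT1670. Capsule 7 had 1 gene that rose and 3 of 26 that fell in the authors' deposited table, or 1 and 2 when adjusted over the list alone (cameraPR adjusted p = 0.0604, median log2 fold -0.71), with folds of 5.56 for BT2872 and 0.234 for BT2887. Capsule 2 had 2 of 18 genes that rose in the authors' deposited table, or 1 when adjusted over the list alone, BT0462 and BT0476 with folds of 2.33 and 2.38. Its test pointed up (cameraPR adjusted p = 0.821) while its median log2 fold was -0.25 in the authors' deposited table. Capsule 6 had 5 of 26 genes that fell in the authors' deposited table, also when adjusted over the list alone, with folds of 0.545 for BT1730 and 0.561 for BT1727. Its test pointed up (cameraPR adjusted p = 0.837), with a median log2 fold of 0.028 and a mean of -0.080 in the authors' deposited table.

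**Figure D2:**
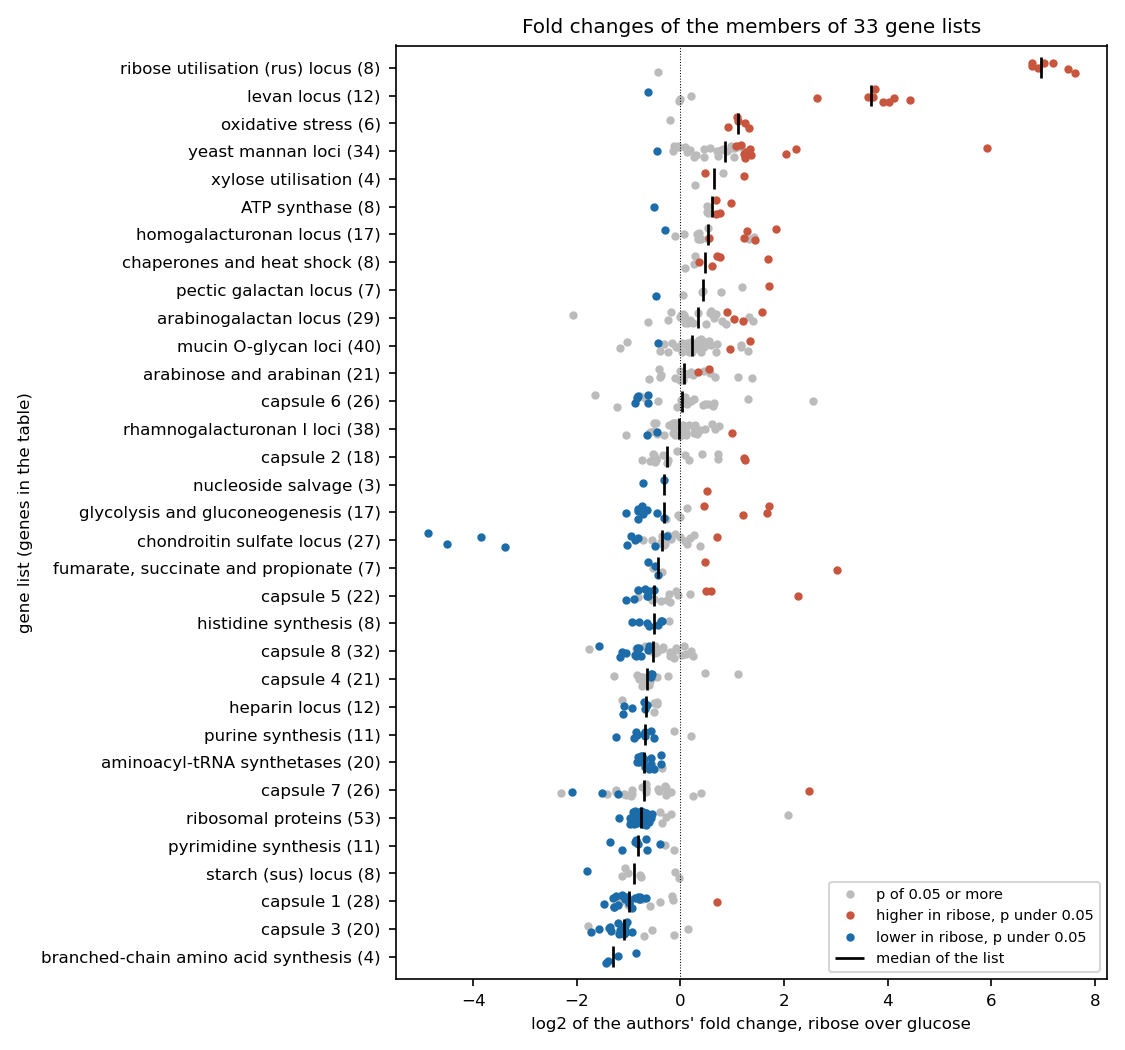
Log2 of the authors' fold change (ribose over glucose) of each member of 33 gene lists, 1 point per gene, with red and blue points for a p under 0.05 in the authors' deposited table, grey points for others and a black bar at each list's median. The ribose locus has the highest median, 6.96, and branched-chain amino acid synthesis the lowest, -1.30.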

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

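All tests in this part were chosen after the results were seen. Some RNA features outside the gene comparison stood higher on ribose. A row for a group II intron (Intron_gpII), 1 of 3 such rows, had a fold of 98.7 in the authors' deposited table. Rows named Cobalamin, a riboswitch family, had p-values under 0.05 in 3 of 6 cases, with folds of 1.66, 2.41 and 1.55 in the authors' deposited table. The RNA of ribonuclease P (RNaseP_bact_a) had a fold of 1.64 and 1 of 3 TPP riboswitch rows a fold of 2.34 in the authors' deposited table.

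The lists for ribosomal proteins, aminoacyl-tRNA synthetases and purine, pyrimidine, histidine and branched-chain amino acid synthesis fell together on ribose. If a few abundant genes had taken reads from all others by 1 factor, genes outside these lists would have fallen alike. The median log2 fold of the 4671 other genes was -0.054 and that of the 107 genes in these lists -0.73 in the authors' deposited table, which argues against that factor as the cause. The fall was not particular to these lists, however. Outside them, the symbol families nuo, trp and mur had median log2 folds of -1.23, -1.13 and -0.76 in the authors' deposited table. Other families, such as isp, aro and rha, stood at -0.28, -0.12 and 0.13 there. A difference in RNA quality or ribosomal RNA depletion cannot be told apart from an effect of the sugar, because 11 of 15 ribosomal RNA rows were listed at a fold of 1 and a score of 0 in the authors' deposited table, and the other 4 had folds from 1.82 to 3.06 with no p under 0.05. A slower growth rate on ribose may lower these genes too, a hypothesis that was not tested.

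Glucose replicate 1 was the lowest glucose library in 54 of the 81 short-list genes. Against a single wrong scaling factor, the SD over genes of its log2 ratio to the other glucose libraries was 0.87, while that SD was 0.63 and 0.50 for glucose replicates 3 and 2, whose ratios include replicate 1, 0.49 for replicate 3 over replicate 2 alone and at most 0.41 for a ribose library. Ribose reads mixed into glucose replicates 2 and 3 would leave genes that fall on ribose higher in replicate 1, but their median log2 ratio was -1.23. For rising genes the median of -0.33 has the sign that mixing gives, and mixing cannot be told apart from other sources there, because the share of ribose reads that the 57 risen genes outside the ribose locus need (median 3.63%, quartiles -0.24% and 5.67%) spans the 0.665% that the locus allows. A culture collected at another point of growth may be the source for all genes, which was not tested.

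Genes past the threshold in limma numbered 81 in the real split of the 6 libraries, and 1 of 10 splits, the real one, gave as many. The highest count in another split was 0. With 10 splits the share cannot be under 0.05, and the authors chose these genes for large differences between the same libraries, which leaves little room for another outcome, so this says nothing about chance.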

How the results depend on the processing

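The settings for centring, all rows, the preset correlation, the scores and leaving out genes listed at a fold of 1 with a score of 0 were chosen after seeing the data. With the replicate number as a block, 81 of 81 short-list genes and 7 ribose locus genes passed limma, and the block changed no other call that could be run. The same 81 and 7 passed with each library left out (highest limma adjusted p from 0.00777 to 0.0270), with pseudocounts of 0.1 and 5, without the trend and at a threshold of 0.01. The authors chose these genes on the same libraries for large changes, which left little room for another outcome. Taking off the filter tested nothing, as it removes none of the 81, and a mean RPKM of at least 10 left 69 genes, and 69 passed. Leaving out glucose replicate 1 moved 8 folds by over 1.5 times: BT3344 to BT3347, with log2 changes of -4.37, -4.56, -3.70 and -4.13 without it, and BT3024 to BT3027, with log2 changes that went from -2.70 to -3.42 for BT3024, -2.39 to -3.05 for BT3025, -2.68 to -3.47 for BT3026 and -2.34 to -3.06 for BT3027. Leaving out ribose replicate 1 moved BT3167 from 3.18 to 2.52. Genes with p under 0.01 in the authors' deposited table numbered 1117 (476 higher, 641 lower). Fold limits of 2, 3 and 10 in place of 5 gave 776, 328 and 33 genes in the authors' deposited table. Counts stayed within 1.5 times with all rows (1992), a recomputed adjustment (2003) and centred folds (1894, with 848 higher and 1046 lower after a shift of the median from -0.073 to 0). List calls fell from 22 to 14 at a preset correlation of 0.05, to 0 at 0.2 (lowest adjusted p = 0.0731) and to 13 with scores in place of ranks; higher correlations widen the test by construction, and the cause of the last was not tested. The lists lost at 0.05 were xylose, mucin, chondroitin, homogalacturonan, arabinogalactan, capsules 4 and 8 and ATP synthase. All 22 list calls held when genes listed at a fold of 1 with a score of 0 were left out. Without the ribose locus 21 of 32 lists passed. With the locus kept, 15 of the 33 lists passed at a threshold of 0.01. Alternative values for the 20 genes named for large changes, the case without the filter aside, kept their call in 220 of 220 cases. Their large changes left little room for another outcome. Alternative values for lists that had passed kept the call in 70 cases and lost it in 39, in the same direction. Of the 70, 22 came from leaving out genes listed at a fold of 1 with a score of 0, and 21 from leaving out the ribose locus. Both settings took few genes out of the ranking. All 39 losses came from the higher preset correlations and from scores in place of ranks. Lists that had not passed stayed so in 55 cases. The replicate block, left-out libraries, filters, pseudocounts and quantile or median scaling were not run for all genes, because their per-library columns matched no labels; scaling was not run on 81 genes chosen for large changes, and fry and an estimated correlation were not run for the other lists. What depth limits is open for the low genes, since absolute depth is unknown.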

Other observations

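All tests in this part were chosen after seeing the data. All 7 nuo genes, which encode an NADH dehydrogenase complex, fell in the authors' deposited table, with a median log2 fold of -1.23 and folds from 0.372 for nuoM to 0.485 for nuoA (cameraPR adjusted p = 0.000888). All 6 nqr genes, for a sodium-pumping NADH:quinone reductase, fell in the authors' deposited table, with a median log2 fold of -1.03 (cameraPR adjusted p = 0.000864). All 7 trp genes of tryptophan synthesis fell in the authors' deposited table, with a median log2 fold of -1.13 (cameraPR adjusted p = 0.000316), and trpF had a fold of 0.430. Of 6 arg genes, which are arginine synthesis genes and the regulator gene argR, 4 fell in the authors' deposited table, argC, argG, argH and argR, with a median log2 fold of -0.99 for the 6 (cameraPR adjusted p = 0.00639). Fatty acid synthesis (fab) genes fell in 4 of 4 cases in the authors' deposited table, with a median log2 fold of -0.68 (cameraPR adjusted p = 0.0287). These were the 5 that passed of 18 symbol families with at least 4 members, and at a preset correlation of 0.05 the same 5 passed, with adjusted p-values from 0.00178 for trp to 0.0427 for fab.

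Past the ribose locus, the next 4 genes also rose in the authors' deposited table, with folds of 2.69 for BT2810, 3.03 for BT2811, 4.20 for BT2812 and 2.80 for BT2813. Runs of at least 4 neighbouring locus tags that changed at least 2-fold in one direction numbered 22 higher and 14 lower in the authors' deposited table. The longest rises outside the ribose locus were BT0434 to BT0443, with a median fold of 3.46 over 10 genes, and BT0446 to BT0454, with 3.33 over 9 genes in the authors' deposited table. BT2287 to BT2294 rose with a median fold of 4.04 over 8 genes in the authors' deposited table. BT0598 to BT0608 fell with a median fold of 0.432 over 11 genes and BT3625 to BT3630 with 0.374 over 6 genes in the authors' deposited table. Same-direction neighbours numbered 290 pairs, against a median of 61 and at most 92 in 10000 permuted orders (permutation p = 0.0001, the smallest they can give). This is consistent with neighbouring genes changing together, as genes of 1 operon may do, but reads spilling over gene ends were not tested.

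The authors' deposited table holds 93 rows with a change of at least 5-fold and a p under 0.05, and 12 of them are not on the short list. They are 11 genes and the intron row, all higher on ribose, with folds from 5.77 to 98.7 in the authors' deposited table. The reason is not given in the sources used here.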
